A study of Mus musculus with 8 samples.

How the data were processed

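Total RNA from excised liver was made into Illumina TruSeq libraries, per the labels' protocols. STAR, Salmon and DESeq2 are named with the genome build mm10 in the submitters' processing notes, without versions. The authors' deposited table is named as DESeq-normalized counts, with 1 row per gene and 8 columns of values.

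The 8 value columns carry library codes. Each code was searched for in every label of the 8 samples and in the series text, and its number in the titles and descriptions after replicate numbers and the age and genotype terms were set aside. All 8 columns were without a match and were not used, in any step. The limma comparisons, gene list tests and overlap of the age and transgenic changes had been planned before the data were examined. So had the seed-site test and the share of the transgenic change left in p53 heterozygous mice. None of these was therefore run.

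Only the identifier and symbol columns were read. Identifiers were matched without version numbers to the GENCODE M21 primary assembly annotation, which is on GRCm38, the assembly also called mm10. Of the 48440 identifiers, 382 were not found there. Coordinates are from that annotation and are counted from 1. Genes of the 36 lists were matched to the table by exact symbol. G6pc and Arntl also entered the lists under the newer symbols G6pc1 and Bmal1, and each symbol was counted.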

Results

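RNA-seq libraries from mouse liver were described for 8 samples on the C57BL/6J background, in 4 groups of 2. The young wild-type group was taken at postnatal day 60 and the old wild-type group at 2 years. The remaining groups were also taken at postnatal day 60: a miR-29-overexpressing transgenic group, and miR-29-overexpressing mice heterozygous for p53. miR-29 is a family of microRNAs that repress many collagen and other extracellular matrix genes, and p53 is a transcription factor that responds to DNA damage and other stresses. The design implies comparisons of old with young wild-type liver, of transgenic with young wild-type liver, and of transgenic liver with and without the loss of 1 copy of p53.

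No expression value is given and none of these comparisons was made. The expression table had 8 columns of values, each headed by a library code, and 0 of the 8 codes appeared in the description of any sample. The age and genotype behind each column were therefore unknown. Assigning columns to groups from their order, or from the levels of the genes under study, was ruled out. The depth of each sample, the spread between replicates and the direction of change of any gene were not analysed here.

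What could be described was the set of genes that the table lists. It held 48440 genes, each with its own Ensembl identifier, and 48058 of these identifiers were found in GENCODE mouse release M21, including 21683 protein-coding genes and 2202 microRNA genes. A row for a gene shows that it was in the annotation used for counting, not that it was expressed.

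The genes that the design turns on were each listed once. Trp53, which encodes p53, has the identifier ENSMUSG00000059552 and lies on chromosome 11 from 69580359 to 69591873 in the GRCm38 (mm10) assembly. The precursors Mir29a and Mir29b-1 lie close together on chromosome 6, from 31062660 to 31062747 and from 31063023 to 31063093. Mir29b-2 and Mir29c form a second cluster on chromosome 1, from 195037040 to 195037120 and from 195037547 to 195037634. The p53 target Cdkn1a, which encodes the cell cycle inhibitor p21, lies on chromosome 17 from 29090976 to 29100727. The fibrillar collagen genes Col1a1 and Col3a1, both known miR-29 targets, lie on chromosome 11 from 94936224 to 94953042 and on chromosome 1 from 45311538 to 45349706. The DNA methyltransferase gene Dnmt3a, also a known miR-29 target, lies on chromosome 12 from 3806007 to 3914443.

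All 24 matrix genes and all 32 other genes chosen as known miR-29 targets had a row in the table, as did all 30 p53 target genes and all 24 senescence genes. Over the 36 lists chosen before the data were examined, 696 of 699 distinct symbols had a row. The symbols without a row were Ahsp, G6pc1 and Bmal1. The lists gave the glucose-6-phosphatase gene as both G6pc and G6pc1 and the clock gene Arntl as both Arntl and Bmal1, so 699 counts symbols rather than genes, and G6pc and Arntl each had a row.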

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

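No paired analysis was possible because no column of values could be matched to a sample, a group or a replicate number. No other setting of the group comparisons was run, for the same reason. The alternatives that follow were chosen after seeing the data. Matching identifiers to the basic annotation also found 48058 genes. Both annotations are of GENCODE release M21, so the equal count does not show how another release would change the match. Allowing the synonyms in the RefSeq gene table raised the list symbols found from 696 to 697. Only this total was recorded, so which of Ahsp, G6pc1 and Bmal1 was gained is not given here. A gain of G6pc1 or Bmal1 would add no gene, because G6pc and Arntl already had rows of their own.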
